A study of Homo sapiens with 48 samples.

How the data were processed

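The study measured RNA in 48 libraries from 2 established breast cancer cell lines, MCF7 and T47D. Each line had 8 groups of 3 libraries: parental cells with vehicle, LY, INX-315, or LY with INX-315, and LYR and LYFR cells with vehicle or INX-315. Groups were read from the sample titles, and the dose of INX-315 (300 nM in MCF7, 100 nM in T47D) and the 7 days of treatment from the labels. Per the submitters' processing notes, RNA was isolated with the NucleoSpin RNA plus kit, 3′ mRNA libraries were made with the QuantSeq FWD kit and sequenced on a NextSeq500 with 75-cycle reads, and reads were aligned with STAR 2.7.5b to hg38 and counted with featureCounts 2.0.1. The annotation release, the strand setting, the handling of reads with several alignments and the use of molecular tags are not given in the sources used here. The deposited table holds raw counts per gene, with no normalization, and 0 columns of other samples.

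The table was checked before use. Its 60656 genes carry versioned Ensembl identifiers, 60445 of which (99.65%, holding 99.97% of the reads) were found without version in the symbol table used here, and 51592 matched GENCODE v44 with the version. Coordinates come from that release. The 44 entries of the pseudoautosomal region of Y held 0 reads. No pair of libraries within a group had identical columns. Total counts per library were 2502535 to 4940878 in MCF7 and 3046218 to 4885243 in T47D, so that 1 count stands for 0.202 to 0.400 CPM (counts scaled to a common library total) in MCF7 and 0.205 to 0.328 CPM in T47D. Protein-coding genes took 88.3 to 93.8% of the counts in MCF7 and 88.7 to 94.5% in T47D, and the 10 most abundant genes of a library took 12.2 to 23.5% and 27.9 to 39.7%.

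Counts were analysed in R 4.3.3. For each line, edgeR 4.0.16 fitted a model with a mean for each of the 8 groups to all 24 libraries, with TMM normalization, the filter filterByExpr (minimum count 10, minimum total 15) and quasi-likelihood F-tests (glmQLFit, glmQLFTest). P-values were adjusted by the method of Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05, and the standard error of a log2 fold change was taken as its size divided by the square root of F. Each line had 11 comparisons fixed before the data were examined: 8 between groups and 3 of the difference between the effects of INX-315 (LYR minus parental cells, LYFR minus parental cells, and with LY minus without LY). The direct comparison of INX-315 with LY was fixed at the same time. Fold changes against a group without counts are given only as bounds, from a floor of 3 counts over the group. Correlations of fold changes across genes (Pearson, Spearman) were computed between conditions whose comparisons share no library, and overlaps of calls were set against the product of the counts of calls divided by the genes tested.

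Before the data were examined, 21 gene lists were written: E2F and DNA replication, G2/M and mitosis, CDK and RB core, histone genes, MHC class I antigen presentation, interferon-stimulated genes, senescence-associated secretory genes, p53 targets, estrogen response, luminal epithelial identity, basal and mesenchymal genes, cholesterol biosynthesis, lysosome, integrated stress and unfolded protein response, AP-1 and MAPK output, hypoxia and glycolysis, drug handling and AHR targets, ribosomal proteins, mitochondrially encoded transcripts, markers of other cell types, and line identity (MTAP, CDKN2A and CDKN2B, tested in T47D). Some genes sit in more than 1 list (CDKN1A, CDKN2A, CDKN2B, GDF15, AREG, VEGFA, SESN2, CTSD and ATF3). Lists were tested with camera in limma 3.58.1 on voom weights, with a preset correlation of 0.01, and adjusted over all lists and comparisons of a line. Members past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone.

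Levels of genes given as a mean ± SD are CPM on library totals scaled by TMM, and those of MTAP and CDKN2A are CPM on plain totals. The rule for named genes was also fixed before the data were examined. For each comparison the text may name the 5 genes with the largest rise and the 5 with the largest fall past the threshold, with a mean log2 CPM of at least 2 and no overlap between the libraries of the groups (for a difference between effects, overlap was not considered), up to 4 members of each list with the largest change past the threshold (or 2 where none passes), and a fixed panel of 28 genes: CDK2, CDK4, CDK6, CCND1, CCNE1, CCNE2, CCNA2, CCNB1, CDK1, CDKN1A, CDKN1B, RB1, E2F1, E2F2, MKI67, MCM2, MYC, ESR1, PGR, GREB1, TFF1, B2M, HLA-A, GDF15, ABCB1, FOXM1, RRM2 and TOP2A. From these the text names 204 pairs of a gene and a comparison.

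Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no filter on low counts, the Wald test of DESeq2 1.42.0 with its default independent filtering, a fit to the libraries of the comparison alone, the replicate number as a block, leaving out each library in turn, and for lists camera with an estimated correlation and fry. Added after seeing the data were fits without the 6 libraries in which more than 20 genes (with a mean log2 CPM of at least 4 over the 24 libraries of the line) lay at least 1 log2 unit below both other libraries of the group, the alternatives of the direct comparisons and of the correlations across genes, and the correlations that involve INX-315 added to LY. Other splits of the libraries were tested with the same model: all 10 for a comparison of 3 with 3, and 100 drawn (seed 11) for a difference between effects, the real split included. Added after seeing the data, the differences between effects were also counted with limma 3.58.1 on log2 CPM (moderated t-tests with a trend) in the data and in 99 draws (seed 13) in which the residuals of the 8 group means were shuffled over the 24 libraries of a line.

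Blocks of neighbouring genes were looked for in windows of 5 Mb with at least 12 genes of mean log2 CPM of at least 3, by 10000 shuffles of the fold changes over genes (seed 7), adjusted over the windows of a comparison. Depth was tested by thinning libraries of the same group (seed 5), and the GC content of the last 600 bases of each gene's transcripts was computed from the GENCODE v44 transcript sequences with Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

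The steps were tested on simulated data with known changes (seed 20). Changes of single genes were placed only in genes above a set mean count, so the shares called do not describe weaker genes. In a simulated comparison of INX-315 with vehicle in MCF7, 69 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were called, with 6.63% false calls, and in T47D 58 of 100 and 95 of 100, with 6.71% false calls. For a simulated difference between effects, 43.5% of genes changed 2-fold were called in MCF7 and 44.0% in T47D. A simulated comparison without changes gave 0 calls in each line in edgeR fitted to all libraries. Fitted to the libraries of that comparison alone, edgeR gave 0 calls in MCF7 and 1 in T47D. DESeq2 over all libraries gave 3 calls for that comparison in MCF7 and 0 in T47D. All simulated libraries were drawn with 1 spread per gene, so none diverged from its group as the 6 libraries did. These rates of false calls may therefore not hold in the data. The list lowered 1.5-fold and both windows lowered 2-fold were called in each line, and no unchanged list or window was. Simulated genes were drawn independently of each other, and both windows were among those with more genes. These results therefore do not cover genes that vary together or small windows. No library was left out of the comparisons, and no gene was left out but by the filter.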

Results

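The data are 48 libraries of 3′ mRNA sequencing from MCF7 and T47D, established breast cancer cell lines that carry the estrogen receptor. They address how such cells respond to INX-315, a selective inhibitor of CDK2, a kinase that drives cells into and through S phase. Each line gave 8 groups of 3 libraries. Parental cells received vehicle, INX-315, LY, or LY with INX-315. LY is read here as abemaciclib, an inhibitor of CDK4 and CDK6, because the labels call abemaciclib-resistant cells LYR, and its dose is not given in the sources used here. LYR cells and LYFR cells, which resist abemaciclib with the estrogen receptor degrader fulvestrant, received vehicle or INX-315. INX-315 was used at 300 nM in MCF7 and at 100 nM in T47D, and cells were treated for 7 days. The vehicle arms of the resistant cells also contained the drugs these cells resist, and the labels do not say whether their INX-315 arms did. Comparisons of those arms can therefore hold a withdrawal of these drugs along with the addition of INX-315. If the drugs were kept, a difference in response from parental cells sets INX-315 on top of these drugs against INX-315 alone. Either way, a trait of the resistant cells cannot be told apart from an effect of the drugs in their medium.

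Total counts per library ran from 2502535 to 4940878 in MCF7 and from 3046218 to 4885243 in T47D, so that 1 count stood for 0.202 to 0.400 and 0.205 to 0.328 CPM. A library detected 15282 to 18090 genes in MCF7 and 15579 to 17335 in T47D, and the filter on low counts left 12969 and 12575 genes for testing. Mitochondrially encoded transcripts took 11.8 to 24.9% of the counts in MCF7 and 30.3 to 44% in T47D. MTAP and CDKN2A, neighbouring genes at the CDKN2A locus, had group means of 0.0743 to 0.639 and 0.133 to 1.51 CPM in MCF7, against 11.7 to 28.2 and 33.8 to 252 CPM in T47D. In 6 libraries, more than 20 genes lay at least 1 log2 unit below both other libraries of their group. These genes numbered 1095 in replicate 1 of the MCF7 LYR vehicle arm, 570 in replicate 3 of parental T47D with INX-315, and 210 in replicate 1 of parental T47D with LY. They numbered 125 in replicate 1 of T47D LYFR with INX-315, 81 in replicate 2 of parental MCF7 with INX-315 and 35 in replicate 3 of MCF7 LYFR with INX-315. Genes as far above both other libraries numbered 838, 56 and 44 in the first 3 of these libraries. Each count of changed genes is therefore also given without these 6 libraries, a choice made after seeing the data. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

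In what follows, a gene's change is the log2 fold change ± its standard error with the adjusted p of edgeR's quasi-likelihood test. Levels are mean CPM ± SD over n = 3 libraries, and a gene is said to rise or fall only where its adjusted p was under 0.05. For a gene list, the members that passed are counted first as adjusted over all genes and then as adjusted over the list alone, and the list's p is the adjusted p of camera.

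INX-315 alone raised GDF15 and the CDK inhibitor genes CDKN1A and CDKN2B in parental MCF7 cells. GDF15, a secreted factor induced by stress, rose from 45.9 ± 2.62 to 436 ± 34.2 CPM (3.25 ± 0.15, adjusted p = 3.31e-13). CDKN1A, which encodes the CDK inhibitor p21, rose by 1.62 ± 0.19, and CDKN2B, which encodes the CDK inhibitor p15, by 1.68 ± 0.11. CDKN1B, which encodes the CDK inhibitor p27, did not pass (-0.17 ± 0.18, adjusted p = 0.599, with a log2 fold change of -0.28 without INX-315 replicate 1). CDK2, the gene of the drug's target (ENSG00000123374.11, chromosome 12, 55966781 to 55972789, plus strand), rose from 134 ± 6.94 to 240 ± 34.8 CPM (0.84 ± 0.15, adjusted p = 0.000321). The cyclin genes CCNE1 (0.88 ± 0.23) and CCND1 (0.65 ± 0.11) also rose. The largest rises were of S100A9, a calcium-binding protein (5.91 ± 0.25, adjusted p = 1.95e-13), TMEM40 (5.08 ± 0.30), SPNS2, a lipid transporter (4.49 ± 0.28), DHRS2 (4.03 ± 0.25) and S100P (3.87 ± 0.17). The largest falls were of KCNJ8, a potassium channel (-4.69 ± 0.43), UGT2B15, a glucuronidation enzyme whose reads may be shared with close paralogs (-4.27 ± 0.35), and OLFML3 (-2.72 ± 0.36). ESR1, the estrogen receptor gene, fell by 1.35 ± 0.16 on the log2 scale while its target TFF1 rose by 1.29 ± 0.15.

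Among the lists, the integrated stress and unfolded protein response rose in parental MCF7 cells with INX-315 in 13 of 19 measured members (15 adjusted over the list alone, median log2 fold change 0.93, adjusted p = 9.13e-11), among them the cystine transporter gene SLC7A11 (2.02 ± 0.14) and CHAC1 (1.92 ± 0.21). Interferon-stimulated genes rose in 16 of 34 (17 adjusted over the list alone, median 1.41, or 1.35 with members absent from a group at their bound, adjusted p = 1.23e-08), with the antiviral sensor gene OAS1 at 2.62 ± 0.29 and IFI6 from 50.2 ± 11.1 to 326 ± 85.1 CPM. Of 17 senescence-associated secretory genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone, median 1.28, adjusted p = 4.30e-07), with the growth factor gene AREG at 1.85 ± 0.16. The p53 target list had 11 rises and 1 fall among 28 (11 and 1 adjusted over the list alone, adjusted p = 2.98e-05), with PLK3 at 2.67 ± 0.38. Lysosome genes rose in 13 of 26 and fell in 1 (17 and 1 adjusted over the list alone, adjusted p = 2.31e-06). The luminal identity list had 11 rises and 3 falls among 24 (14 and 3 adjusted over the list alone, adjusted p = 0.000943). AP-1 and MAPK output had 8 rises and 2 falls among 21 (12 and 2 adjusted over the list alone, adjusted p = 0.00111). Mitochondrially encoded transcripts rose in 11 of 13 (12 adjusted over the list alone, adjusted p = 1.02e-09) and ribosomal protein genes fell in 5 of 39 (5 adjusted over the list alone, median -0.24, adjusted p = 1.90e-05).

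The cell cycle lists did not fall in parental MCF7 cells with INX-315. Of 45 E2F and DNA replication genes, 5 rose and none fell (5 adjusted over the list alone, adjusted p = 0.152, 0.000276 to 0.217 over 8 alternatives). The ribonucleotide reductase gene RRM2 (ENSG00000171848.15, chromosome 2, 10120698 to 10211725, plus strand) rose by 1.51 ± 0.14. The G2/M and mitosis list lay higher (2 of 39 rose, 0 adjusted over the list alone, median 0.30, adjusted p = 0.0196). Its call was lost with DESeq2's values (adjusted p = 0.105) and at an adjusted p = 0.189 with an estimated correlation (0.00114 to 0.189 over 8 alternatives). Hypoxia and glycolysis genes rose in 9 of 23 (9 adjusted over the list alone, adjusted p = 0.0166, or adjusted p = 0.202 with an estimated correlation, 0.000642 to 0.202 over 8 alternatives). Of 15 genes of MHC class I antigen presentation, 5 rose (5 adjusted over the list alone), among them B2M (0.82 ± 0.12) and HLA-A (0.70 ± 0.16, with reads that other HLA genes may share). The list did not pass in camera as planned (adjusted p = 0.120). It passed in camera with only the libraries of the comparison (adjusted p = 0.0212), without the 6 libraries (adjusted p = 0.0323) and in fry (adjusted p = 0.000709, 0.000709 to 0.154 over 8 alternatives). In all, 1950 genes changed, 1278 of them upward, and 3353 changed without the 6 libraries.

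In parental T47D cells, INX-315 alone raised interferon-stimulated genes. IFI6 (ENSG00000126709.15, chromosome 1, 27666064 to 27672212, minus strand) rose from 69.4 ± 13.7 to 278 ± 67.1 CPM (adjusted p = 1.94e-06), OAS1 by 2.28 ± 0.32, OAS2 by 1.97 ± 0.29 and IFIT1 by 2.44 ± 0.40. The list had 13 rises among 35 (20 adjusted over the list alone, median 1.25, adjusted p = 8.12e-20). Outside it, the adhesion gene MCAM rose (2.35 ± 0.32), and the keratin gene KRT15 (-1.90 ± 0.29), the fatty acid transporter gene CD36 (-1.63 ± 0.28) and DHRS2 (-1.52 ± 0.27) fell. Ribosomal protein genes fell in 8 of 39 (19 adjusted over the list alone, median -0.27, adjusted p = 2.18e-16), and senescence-associated secretory genes rose in 3 of 17 (5 adjusted over the list alone, adjusted p = 0.000811). No member of the G2/M list passed among 39 in edgeR's test (0 adjusted over the list alone, median -0.13, adjusted p = 0.164). Yet fry called the list lower (adjusted p = 0.0283) and so did camera without the filter (adjusted p = 0.0110, 0.0110 to 0.265 over 8 alternatives). CDKN1A stood at 87.0 ± 21.9 against 55.5 ± 3.61 CPM, which did not pass (0.65 ± 0.17, adjusted p = 0.0546). It passed with DESeq2 size factors (adjusted p = 0.0488), with DESeq2's Wald test (adjusted p = 0.0253) and without INX-315 replicate 1 or 2 (adjusted p = 0.0356 and 0.0290). Its adjusted p ran from 0.0253 to 0.416 over 12 alternatives.

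The size of that T47D response rests on few libraries. Changed genes numbered 189, 123 of them upward, but 64, 67 and 62 without vehicle replicate 1, 2 or 3, 340 without INX-315 replicate 1 and 509 without the 6 divergent libraries. The upward share of 65.1% was 50% without vehicle replicate 3 or INX-315 replicate 1, 51.1% without the 6 libraries and 47.7% without the filter on low counts. With a fit to the 6 libraries of this comparison alone, edgeR called 0 genes, with 954 of 11072 at an unadjusted p under 0.05, while DESeq2 over all 24 libraries called 300. Each gene named as changed in this comparison lost its call in that smaller fit (adjusted p of 0.0513 to 0.304) at nearly the same log2 fold change, as with IFIT1 at 2.45 ± 0.60, MCAM at 2.35 ± 0.32, OAS1 at 2.27 ± 0.40, OAS2 at 1.97 ± 0.35, KRT15 at -1.91 ± 0.26, CD36 at -1.63 ± 0.29 and DHRS2 at -1.52 ± 0.19.

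LY lowered the cell cycle genes and raised interferon and antigen presentation genes in parental MCF7 cells. The proliferation marker MKI67 fell from 137 ± 8.35 to 13.7 ± 4.36 CPM (-3.31 ± 0.24, adjusted p = 9.68e-11), RRM2 from 100 ± 5.14 to 12.4 ± 0.900 CPM (-3.01 ± 0.16), and the mitotic kinase gene AURKB fell by 4.43 ± 0.37 on the log2 scale. All 39 measured G2/M genes fell (39 adjusted over the list alone, median -2.96, adjusted p = 1.78e-25), as did 43 of 45 E2F and DNA replication genes (44 adjusted over the list alone, median -2.08, adjusted p = 2.36e-25). OAS2 rose from 0.346 ± 0.227 to 251 ± 31.8 CPM (9.38 ± 0.26, adjusted p = 1.64e-17), and RSAD2, an antiviral enzyme, from no counts to 46.8 ± 8.49 CPM, at least 224-fold higher. All 34 interferon-stimulated genes rose (34 adjusted over the list alone, median 6.20, or 6.02 with absent members at their bound, adjusted p = 5.45e-33). All 15 antigen presentation genes rose too (15 adjusted over the list alone, median 2.39, adjusted p = 1.41e-12), with B2M at 2.35 ± 0.12, the peptide transporter gene TAP1 at 4.19 ± 0.16 and the immunoproteasome gene PSMB9 at 4.67 ± 0.24.

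Other groups moved with LY in parental MCF7 cells. Senescence-associated secretory genes rose in 12 of 17 and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 1.13e-08), among them the chemokine gene CCL5 (5.38 ± 0.21), and GDF15 (3.82 ± 0.15). SERPINE1, an inhibitor of plasminogen activators, went from no counts to 9.91 ± 0.831 CPM, at least 47.4-fold higher. Lysosome genes rose in 20 of 26 (22 adjusted over the list alone with 1 fall, adjusted p = 1.61e-08). Luminal identity genes rose in 13 of 24 with 3 falls (13 and 3 adjusted over the list alone, adjusted p = 0.0104), with ESR1 at -1.82 ± 0.16. Drug handling and AHR targets rose in 8 of 14 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.0189), with the aldehyde dehydrogenase gene ALDH1A3 at 5.14 ± 0.25. Ribosomal protein genes fell in 37 of 39 (38 adjusted over the list alone, median -0.99, adjusted p = 6.68e-17). Mitochondrially encoded transcripts rose in 11 of 13 (11 adjusted over the list alone, adjusted p = 2.81e-05, or adjusted p = 0.136 with an estimated correlation, 1.53e-10 to 0.136 over 8 alternatives). CCND1 (0.86 ± 0.11), CDK6 (0.93 ± 0.12), CDKN1A (1.11 ± 0.19) and CDKN2B (2.68 ± 0.11) rose, while CDK4 (-0.93 ± 0.12) and CDK2 (-0.83 ± 0.15) fell. The list of the CDK and RB core went both ways, with 6 rises and 13 falls among 28 (6 and 13 adjusted over the list alone, adjusted p = 0.132, 0.0123 to 0.401 over 8 alternatives). Histone genes did as well, with 8 rises and 3 falls among 13 (8 and 4 adjusted over the list alone, adjusted p = 0.0904, 1.17e-09 to 0.107 over 8 alternatives). H4C8 stood at 2.23 ± 0.16 and H4C3 at -2.95 ± 0.33, although copies of histone genes can share reads. LY changed 5298 genes, 2772 of them upward, and 7002 without the 6 libraries.

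In parental T47D cells, LY also lowered RRM2 (-3.52 ± 0.17, adjusted p = 2.21e-15) and MKI67, from 217 ± 8.70 to 20.8 ± 5.29 CPM (-3.39 ± 0.18). G2/M genes fell in 36 of 39 (36 adjusted over the list alone, median -1.98, adjusted p = 2.34e-31) and E2F genes in 40 of 45 (42 adjusted over the list alone, median -1.38, adjusted p = 3.78e-26). IFI27 rose from 4.88 ± 1.48 to 1261 ± 182 CPM (7.99 ± 0.53) and IFIT3 by 7.67 ± 0.28. Interferon-stimulated genes rose in 34 of 35 (34 adjusted over the list alone, median 4.86, adjusted p = 1.03e-43). All 16 antigen presentation genes rose (16 adjusted over the list alone, median 1.77, adjusted p = 1.06e-12), with HLA-A at 1.98 ± 0.17. The melanosomal and lysosomal glycoprotein gene GPNMB rose by 4.43 ± 0.22 among 14 rises in 27 lysosome genes (15 rises and 2 falls adjusted over the list alone, adjusted p = 8.73e-06). CHAC1 rose by 2.80 ± 0.32 among 12 rises and 1 fall in 20 stress response genes (12 and 1 adjusted over the list alone, adjusted p = 8.77e-06). Estrogen response genes fell in 13 of 34 and rose in 3 (13 and 4 adjusted over the list alone, adjusted p = 0.00461), with ESR1 at -1.12 ± 0.18. Senescence-associated secretory genes rose in 10 of 17 and fell in 2 (10 and 2 adjusted over the list alone, adjusted p = 1.91e-05). All 39 ribosomal protein genes fell (39 adjusted over the list alone, median -0.85, adjusted p = 3.77e-26). CDKN1A fell (-0.74 ± 0.18) while CDKN2B (2.37 ± 0.26) and CCND1 (1.26 ± 0.10) rose. LY changed 3589 genes in T47D, 1826 of them upward, and 4469 without the 6 libraries, 2135 of them upward.

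INX-315 and LY differed in parental cells when set against each other directly. In MCF7, RRM2 was at 286 ± 12.1 CPM with INX-315 and 12.4 ± 0.900 with LY (4.52 ± 0.16, adjusted p = 1.57e-15). In all, 39 of 39 G2/M genes (39 adjusted over the list alone, median 3.22, adjusted p = 6.05e-34) and 43 of 45 E2F genes (45 adjusted over the list alone, adjusted p = 8.10e-33) were higher with INX-315. Interferon-stimulated genes were lower with INX-315 in 33 of 34 (33 adjusted over the list alone, median -4.70, or -4.66 with absent members at their bound, adjusted p = 2.23e-40), with IFIT3 at -6.95 ± 0.23. In T47D, 34 of 39 G2/M genes (36 adjusted over the list alone, median 1.96, adjusted p = 7.02e-34) were higher with INX-315 than with LY. Interferon-stimulated genes were lower in 34 of 35 and higher in 1 (34 and 1 adjusted over the list alone, median -3.65, adjusted p = 4.15e-46). CDKN1A was higher with INX-315 in T47D (1.39 ± 0.18), and CDK6 was lower with it in MCF7 (-1.17 ± 0.12). The direct comparison gave 4197 genes in MCF7 (5348 without the 6 libraries) and 3102 in T47D (3502 without them). The T47D count was 940 with a fit to the 6 libraries of the comparison alone.

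**Figure D1:**
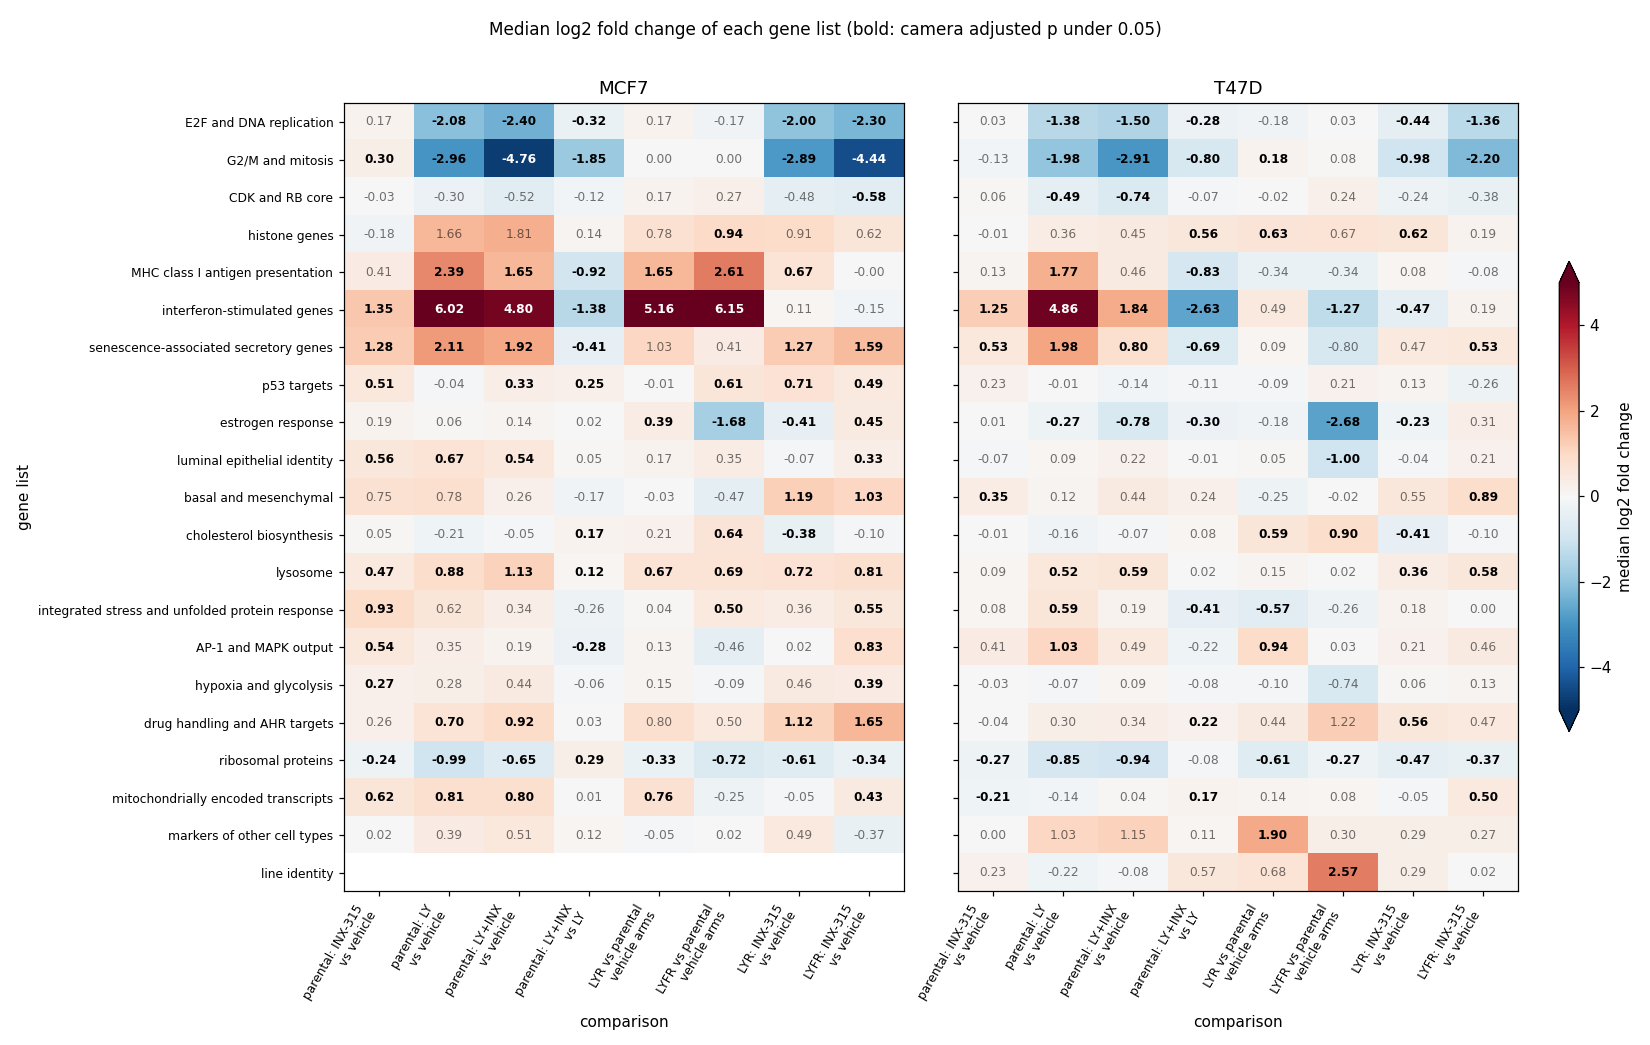
Heat map of the median log2 fold change of each gene list (vertical axis) in the 8 comparisons of groups per line (horizontal axis), with members at 0 counts in a group set to their bound and values in bold where camera's adjusted p was under 0.05. In MCF7 the G2/M list stands at 0.30 with INX-315 alone, -2.96 with LY and -4.44 with INX-315 in LYFR cells.

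Adding INX-315 to LY lowered the mitotic genes further and lowered interferon and antigen presentation genes in MCF7. FOXM1, a transcription factor of the G2/M genes, stood at 50.8 ± 2.11 CPM with vehicle, 4.80 ± 1.31 with LY and 0.924 ± 0.290 with both drugs (-2.33 ± 0.28 for both drugs against LY, adjusted p = 8.92e-06). RRM2 fell further (-1.71 ± 0.20), as did the replication factor gene MCM10 (-2.60 ± 0.53) and MKI67 (-1.85 ± 0.30). G2/M genes fell in 17 of 39 (33 adjusted over the list alone, median -1.85, adjusted p = 1.63e-28) and E2F genes in 8 of 45 (9 adjusted over the list alone, adjusted p = 2.53e-07). OAS2 fell from 251 ± 31.8 to 36.7 ± 3.43 CPM (-2.77 ± 0.15, adjusted p = 5.08e-11) and PSMB9 from 38.0 ± 3.69 to 6.19 ± 0.712 (-2.62 ± 0.19). Interferon-stimulated genes fell in 30 of 34 (33 adjusted over the list alone, median -1.38, adjusted p = 9.84e-82). Antigen presentation genes fell in 10 of 15 (12 adjusted over the list alone, median -0.92, adjusted p = 1.27e-23), and B2M fell by 1.06 ± 0.12 on the log2 scale. Of the p53 targets 4 of 28 rose (4 adjusted over the list alone, adjusted p = 6.74e-06), with ZMAT3 at 1.14 ± 0.16. In addition 5 of 39 ribosomal protein genes rose (13 adjusted over the list alone, median 0.29, adjusted p = 2.17e-13). TFF3, a secreted trefoil peptide (1.44 ± 0.19), and the iron-regulated aconitase gene ACO1 (1.85 ± 0.22) rose too.

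That comparison gave 312 genes in MCF7, 219 of them downward, against 189 without LY replicate 2, 179 and 171 without replicate 2 or 3 of both drugs, 1303 without the 6 libraries and 1448 with a fit to its own 6 libraries. The last 2 fits were more even, with 572 upward and 731 downward without the 6 libraries, and 659 upward and 789 downward in its own libraries. Against vehicle, both drugs together changed 5218 genes in MCF7 (7069 without the 6 libraries). All 39 G2/M genes were lower than with vehicle (39 adjusted over the list alone, median -4.76, adjusted p = 3.78e-29), with PLK1 at -6.00 ± 0.32 and CDK1 at -5.30 ± 0.34. In the same comparison 31 of 34 interferon-stimulated genes were higher (32 adjusted over the list alone, median 5.05, or 4.80 with absent members at their bound, adjusted p = 4.64e-24).

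Adding INX-315 to LY in T47D lowered interferon-stimulated genes in 32 of 35 (33 adjusted over the list alone, median -2.63, adjusted p = 1.72e-84). IFIT3 fell from 429 ± 38.0 to 32.3 ± 6.86 CPM (-3.74 ± 0.20, adjusted p = 6.48e-13), and LGALS9, a galectin, fell by 3.89 ± 0.45 on the log2 scale. Antigen presentation genes fell in 11 of 16 (13 adjusted over the list alone, median -0.83, adjusted p = 1.05e-19), with HLA-A at -1.48 ± 0.17 and B2M at -1.40 ± 0.17. G2/M genes fell in 18 of 39 (22 adjusted over the list alone, median -0.80, adjusted p = 4.49e-11), with FOXM1 at -1.70 ± 0.26 and CDK1 at -1.30 ± 0.20. Stress response genes fell in 6 of 20 (7 falls and 1 rise adjusted over the list alone, adjusted p = 0.000301), with PHGDH, an enzyme of serine synthesis, at -1.19 ± 0.15. CDKN1A (-1.23 ± 0.20) and AREG (-1.44 ± 0.17) fell, and DOCK1, which encodes a guanine nucleotide exchange factor (2.04 ± 0.28), and ACO1 (1.86 ± 0.22) rose. These were among 562 changed genes, 345 of them downward. The count was 341 without LY replicate 1, 328, 356 and 302 without replicate 1, 2 or 3 of both drugs, 272 with a fit to its own libraries and 1100 without the 6 divergent ones, where 584 were upward and 516 downward. Against vehicle, both drugs changed 4238 genes (5643 without the 6 libraries). G2/M genes were then lower in 37 of 39 (37 adjusted over the list alone, median -2.91, adjusted p = 9.37e-32), CDK6 higher (2.31 ± 0.28) and CDKN1A lower (-1.97 ± 0.19).

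The effect of INX-315 depended on whether LY was present. In MCF7 the difference between the effects passed for 1453 genes (2918 without the 6 libraries, 2747 with a fit to its own libraries). Interferon-stimulated genes responded more negatively with LY in 25 of 34 (28 adjusted over the list alone, median -2.80, adjusted p = 1.19e-27), as did G2/M genes in 30 of 39 (34 adjusted over the list alone, median -2.04, adjusted p = 9.63e-17). So did 11 of 17 senescence-associated secretory genes (12 adjusted over the list alone, adjusted p = 9.13e-11) and 11 of 19 stress response genes (13 adjusted over the list alone, adjusted p = 5.71e-09). The differences were -5.45 ± 0.43 for OAS2, -3.22 ± 0.24 for RRM2, -2.76 ± 0.19 for GDF15 and -1.43 ± 0.26 for CDKN1A (adjusted p = 0.000564). In T47D the difference passed for 594 genes, led by interferon-stimulated genes in 31 of 35 (34 adjusted over the list alone, median -3.60, adjusted p = 1.46e-53), with IFIT3 at -5.68 ± 0.39, GDF15 at -2.75 ± 0.44 and CDKN1A at -1.88 ± 0.26. G2/M genes responded more negatively with LY in 10 of 39 there (19 adjusted over the list alone, median -0.63, adjusted p = 7.81e-07). The T47D count was 373, 381 and 319 without vehicle replicate 1, 2 or 3, 366 without LY replicate 1, 953 without INX-315 replicate 1, 378 and 355 without replicate 1 or 3 of both drugs, 184 with a fit to its own libraries and 863 without the 6 libraries.

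Resistant cells were compared with parental cells in their vehicle arms, which asks what differs in cells that grow with abemaciclib. The parental vehicle libraries are shared by the LYR and LYFR comparisons, so likeness between them can come in part from those libraries. In MCF7 LYR cells, CDKN1B, which encodes the CDK inhibitor p27 (ENSG00000111276.11, chromosome 12, 12685498 to 12722369, plus strand), stood at 12.6 ± 5.12 against 71.5 ± 0.811 CPM (-2.44 ± 0.20, adjusted p = 2.74e-09), while CCNE1 was higher (1.84 ± 0.22). IFI27 was at 3603 ± 483 against 4.33 ± 2.10 CPM (9.66 ± 0.25). Of the lists, 33 of 34 interferon-stimulated genes (33 adjusted over the list alone, median 5.16, adjusted p = 9.57e-36) and 14 of 15 antigen presentation genes (14 adjusted over the list alone, median 1.65, adjusted p = 4.54e-11) were higher. The transcription factor gene ASCL1 (8.64 ± 0.34), GDF15 (3.43 ± 0.15) and the mucin gene MUC1 (3.49 ± 0.28) were higher. The phosphatase gene DUSP6 (-2.93 ± 0.31), the caveolin gene CAV1 (-3.15 ± 0.17) and the adenylate kinase gene AK7 (-4.54 ± 0.28) were lower. Estrogen response genes were higher in 16 of 33 and lower in 5 (16 and 5 adjusted over the list alone, adjusted p = 0.00890), with TFF1 at 0.87 ± 0.15. The G2/M list did not differ by the test (4 up and 4 down of 39, 1 and 1 adjusted over the list alone, adjusted p = 0.678), but camera called it lower without the filter (adjusted p = 0.0330, 0.0330 to 0.986 over 8 alternatives). In all, 4746 genes differed (6072 without the 6 libraries, 1539 with a fit to the 6 libraries of the comparison).

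MCF7 LYFR cells, grown with fulvestrant as well, had lower estrogen response genes than parental cells in 25 of 33 with 1 higher (25 and 1 adjusted over the list alone, median -1.68, adjusted p = 2.77e-15). TFF1 was at 14.7 ± 3.13 against 4794 ± 180 CPM (-8.34 ± 0.21, adjusted p = 8.00e-19), GREB1 at -5.46 ± 0.23, AREG at -6.01 ± 0.22 and ESR1 at -2.96 ± 0.17. GFRA1, a receptor subunit of GDNF, was lower (-9.33 ± 0.22). Interferon-stimulated genes were higher in 33 of 34 (33 adjusted over the list alone, median 6.48, or 6.15 with absent members at their bound, adjusted p = 8.83e-34), RSAD2 from no counts to 258 ± 19.1 CPM, at least 1235-fold higher. All 15 antigen presentation genes were higher (15 adjusted over the list alone, median 2.61, adjusted p = 6.12e-14). CDKN1B was lower (-2.34 ± 0.20), and CCNE2 (1.55 ± 0.30) was higher. Genes of cholesterol biosynthesis were higher in 13 of 22 and lower in 1 (14 and 1 adjusted over the list alone, adjusted p = 0.000282), with INSIG1 at 1.89 ± 0.18. Of 5521 genes that differed, 2784 were higher, and 7331 differed without the 6 libraries.

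T47D LYR cells had AREG and its relatives EPGN and EREG, ligands of the EGF receptor, far above the parental level. AREG was at 426 ± 6.87 against 9.85 ± 0.269 CPM (5.43 ± 0.18, adjusted p = 2.43e-18), and EPGN at 10.20 ± 0.42. EREG went from no counts to 31.1 ± 1.89 CPM, at least 130-fold higher. CDK6 (2.20 ± 0.28) and CDKN2B (2.64 ± 0.25) were higher. CDKN1A (-2.47 ± 0.20), CDKN1B (-1.16 ± 0.26, adjusted p = 0.00121) and the progesterone receptor gene PGR (-1.84 ± 0.12) were lower, and so was the immunoproteasome gene PSMB8 (-3.18 ± 0.35). RB1, the retinoblastoma gene, was at 12.1 ± 3.54 against 28.1 ± 4.23 CPM (-1.20 ± 0.36, adjusted p = 0.0106), a call lost without replicate 3 of the LYR vehicle arm (adjusted p = 0.0706, from 1.18e-07 to 0.0706 over 12 alternatives). Cholesterol genes were higher in 13 of 23 and lower in 1 (16 and 1 adjusted over the list alone, adjusted p = 1.25e-06). Stress response genes were lower in 11 of 20 and higher in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.00154). Of 3 measured markers of other cell types 2 were higher (2, and 1 lower, adjusted over the list alone, adjusted p = 0.0240, or adjusted p = 0.0547 with an estimated correlation, 1.19e-08 to 0.0985 over 7 alternatives). Their median of 1.90 turned to -1.01 without the filter. COL3A1, a fibrillar collagen, went from no counts to 21.4 ± 2.17 CPM, at least 88.4-fold higher, and TWIST1 was also higher (5.49 ± 0.33). Interferon-stimulated genes were higher in 8 of 35 and lower in 3 (9 and 4 adjusted over the list alone, adjusted p = 0.0564, 0.0165 to 0.352 over 8 alternatives). In all, 3927 genes differed (5438 without the 6 libraries).

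T47D LYFR cells had PGR at 5.62 ± 1.26 against 954.5 ± 38.7 CPM (-7.38 ± 0.17, adjusted p = 2.49e-22), ESR1 at -3.63 ± 0.21, and GREB1 at -6.59 ± 0.31. Estrogen response genes were lower in 27 of 34 and higher in 3 (27 and 3 adjusted over the list alone, median -2.68, adjusted p = 1.03e-14). Luminal identity genes were lower in 15 of 24 and higher in 2 (15 and 3 adjusted over the list alone, adjusted p = 2.93e-07). The aldo-keto reductase genes AKR1C1 (7.64 ± 0.38) and AKR1C2 (6.67 ± 0.42), close paralogs that may share reads, were higher, as were CCL2 (6.68 ± 0.47), CCNE1 (1.75 ± 0.25) and E2F3 (1.97 ± 0.18). All 3 genes of the line identity list were higher (3 adjusted over the list alone, adjusted p = 0.00786), CDKN2A by 2.57 ± 0.35 and CDKN2B by 3.60 ± 0.24. With INX-315 in parental T47D cells, no member of that list passed in edgeR (0 of 3, 0 adjusted over the list alone, adjusted p = 0.960). Cholesterol genes were higher in 15 of 23 and lower in 1 (15 and 1 adjusted over the list alone, adjusted p = 2.36e-05), and TIMP1 lower (-6.91 ± 0.35). Interferon-stimulated genes were lower in 19 of 35 and higher in 2 (22 and 2 adjusted over the list alone, median -1.27, adjusted p = 0.00116, or adjusted p = 0.123 with an estimated correlation, 2.47e-06 to 0.123 over 8 alternatives). In all, 5190 genes differed (6624 without the 6 libraries).

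INX-315 lowered mitotic and replication genes in MCF7 LYR cells. MKI67 fell from 128 ± 25.3 to 17.3 ± 4.78 CPM (-2.88 ± 0.23, adjusted p = 3.37e-09), RRM2 from 172 ± 27.2 to 19.8 ± 0.904 (-3.12 ± 0.15), and CDC20, an activator of mitotic exit, fell by 4.20 ± 0.24 on the log2 scale. All 39 G2/M genes fell (39 adjusted over the list alone, median -2.89, adjusted p = 3.28e-35) and 44 of 45 E2F genes (44 adjusted over the list alone, median -2.00, adjusted p = 8.58e-33). CDK2 fell (-1.45 ± 0.16), and CDKN1A (1.76 ± 0.19), GDF15 (2.58 ± 0.14) and the p53 target BBC3 (1.85 ± 0.17) rose. The p53 list had 17 rises and 2 falls among 28 (20 and 2 adjusted over the list alone, median 0.71, adjusted p = 2.53e-07). Lysosome genes rose in 19 of 26 and fell in 1 (20 and 1 adjusted over the list alone, adjusted p = 1.23e-09). Basal and mesenchymal genes rose in 9 of 15 (10 adjusted over the list alone, adjusted p = 4.75e-06), with the matrix gene TGFBI at 2.52 ± 0.12. Drug handling genes rose in 10 of 14 (12 adjusted over the list alone, adjusted p = 3.90e-07), with the efflux pump gene ABCG2 at 2.60 ± 0.26. Estrogen response genes fell in 17 of 33 and rose in 2 (19 and 3 adjusted over the list alone, adjusted p = 0.000207), with TFF1 at -1.28 ± 0.15 and MYB at -2.17 ± 0.21. The largest rises were of the adhesion gene CEACAM1 (3.80 ± 0.21), MUC20 (3.63 ± 0.32) and the defensin gene DEFB1 (3.34 ± 0.35). In all, 4152 genes changed (5273 without the 6 libraries, 933 with a fit to the 6 libraries of the comparison, where replicate 1 of the vehicle arm is the library with 1095 low genes).

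The response of MCF7 LYR cells differed from that of parental cells for 2717 genes (4066 without the 6 libraries, 1455 with a fit to its own libraries). As the LYR vehicle arm held abemaciclib, this difference may come from the drug as well as from the cells. With LY in parental cells the G2/M list also responded more negatively (median difference -2.04). All 39 G2/M genes responded more negatively in LYR cells (39 adjusted over the list alone, median -3.23, adjusted p = 2.15e-40), as did 42 of 45 E2F genes (43 adjusted over the list alone, adjusted p = 5.80e-33) and 15 of 34 interferon-stimulated genes with 1 in the other direction (17 and 1 adjusted over the list alone, adjusted p = 9.55e-06). The difference was -4.63 ± 0.21 for RRM2, -2.29 ± 0.22 for CDK2, -2.56 ± 0.21 for TFF1 and 6.27 ± 0.39 for ANKRD1, a target of YAP signalling (adjusted p = 3.67e-10).

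In T47D LYR cells, INX-315 lowered BIRC5, an inhibitor of apoptosis made in mitosis, from 134 ± 18.9 to 51.6 ± 1.03 CPM (-1.37 ± 0.15, adjusted p = 7.25e-07), MKI67 (-1.10 ± 0.16), RRM2 (-0.87 ± 0.14) and CCND1 (-0.70 ± 0.10). G2/M genes fell in 32 of 39 (37 adjusted over the list alone, median -0.98, adjusted p = 7.24e-42) and E2F genes in 12 of 45 (16 falls and 2 rises adjusted over the list alone, adjusted p = 3.08e-10). CDKN1A rose (0.93 ± 0.21), as did the keratin gene KRT4 (3.18 ± 0.30) and BCAS1 (2.59 ± 0.24). Cholesterol genes fell in 9 of 23 (10 adjusted over the list alone, adjusted p = 8.24e-08), with EBP at -1.08 ± 0.15. Histone genes rose in 7 of 13 (7 rises and 1 fall adjusted over the list alone, adjusted p = 2.51e-05), with H4C8 at 2.62 ± 0.22. Lysosome genes rose in 9 of 27 (14 adjusted over the list alone, adjusted p = 1.15e-09), with GPNMB at 1.69 ± 0.17. Interferon-stimulated genes fell in 6 of 35 (9 falls and 2 rises adjusted over the list alone, median -0.47, adjusted p = 0.000994, or adjusted p = 0.123 with an estimated correlation, 0.000568 to 0.123 over 8 alternatives). Ribosomal protein genes fell in 21 of 39 (37 adjusted over the list alone, median -0.47, adjusted p = 5.32e-24). In all, 980 genes changed, 602 of them upward, but 645 and 630 without vehicle replicate 1 or 3, 606 and 595 without INX-315 replicate 2 or 3, 2502 with a fit to the 6 libraries of the comparison and 2409 without the 6 divergent libraries.

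For T47D LYR against parental cells the difference in response passed for 372 genes, but 243 and 239 without replicate 2 or 3 of the parental vehicle arm and 1106 without the 6 libraries. G2/M genes responded more negatively in LYR cells in 18 of 39 (26 adjusted over the list alone, median -0.90, adjusted p = 1.32e-29). Interferon-stimulated genes did so in 15 of 35 (18 adjusted over the list alone, median -1.42, adjusted p = 5.29e-19). RRM2 differed by -1.49 ± 0.19, CCND1 by -0.96 ± 0.14, IFIT1 by -3.96 ± 0.56 and HSD17B1, an enzyme of estradiol synthesis, by 3.12 ± 0.27 (adjusted p = 3.81e-08).

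INX-315 lowered CDK1 in MCF7 LYFR cells from 30.2 ± 1.23 to 0.350 ± 0.128 CPM (-6.33 ± 0.39, adjusted p = 1.72e-11), CCNA2, the cyclin A gene (-6.32 ± 0.46), and FOXM1 (-5.43 ± 0.21). All 39 G2/M genes (39 adjusted over the list alone, median -4.44, adjusted p = 8.61e-40) and all 45 E2F genes fell (45 adjusted over the list alone, median -2.30, adjusted p = 1.76e-37), and CDK2 fell by 1.80 ± 0.16 on the log2 scale. Senescence-associated secretory genes rose in 15 of 17 and fell in 1 (15 and 1 adjusted over the list alone, median 1.59, adjusted p = 1.32e-08), with the activin gene INHBA at 3.86 ± 0.23 and GDF15 at 3.03 ± 0.14. CDKN1A rose (1.85 ± 0.19), TGFBI rose (3.66 ± 0.14), and the laminin gene LAMC2 rose (3.43 ± 0.21) among 9 rises and 1 fall in 15 basal and mesenchymal genes (9 and 1 adjusted over the list alone, adjusted p = 1.99e-05). SPRR1B, a cornified envelope protein of a family of close paralogs, rose by 5.01 ± 0.48, and the siderophore-binding gene LCN2 by 4.26 ± 0.31. Estrogen response genes rose in 14 of 33 and fell in 3 (15 and 4 adjusted over the list alone, adjusted p = 0.00527), with CTSD at 1.61 ± 0.27. Interferon-stimulated genes did not pass (2 rises and 5 falls of 34, 2 and 3 adjusted over the list alone, adjusted p = 0.175), though camera called them lower without the filter (adjusted p = 0.0269, 0.0269 to 0.490 over 8 alternatives). In all, 3873 genes changed, 2189 of them upward (5317 without the 6 libraries). The response differed from that of parental cells for 2089 genes (3450 without the 6 libraries, 3208 with a fit to its own libraries). Among them were all 39 G2/M genes (39 adjusted over the list alone, median -4.63, adjusted p = 3.16e-53), with RRM2 at -6.19 ± 0.22, CDK1 at -7.01 ± 0.46 and CDK2 at -2.63 ± 0.22.

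In T47D LYFR cells, INX-315 lowered CCNA2 from 49.7 ± 2.32 to 4.77 ± 0.616 CPM (-3.38 ± 0.21, adjusted p = 1.25e-11), MKI67 (-2.60 ± 0.17), RRM2 (-2.54 ± 0.16) and CDK2 (-0.95 ± 0.17). G2/M genes fell in 38 of 39 (38 adjusted over the list alone, median -2.20, adjusted p = 7.60e-48) and E2F genes in 40 of 45 (44 adjusted over the list alone, median -1.36, adjusted p = 8.08e-36). CCND1 rose from 263 ± 14.6 to 815 ± 17.6 CPM (1.63 ± 0.10), CDKN2B by 2.02 ± 0.18 and the metallocarboxypeptidase gene CPA4 by 3.40 ± 0.21. Lysosome genes rose in 15 of 27 (20 adjusted over the list alone, median 0.58, adjusted p = 3.90e-12), with the saposin gene PSAP at 1.48 ± 0.14. Basal and mesenchymal genes rose in 5 of 12 (5 adjusted over the list alone, adjusted p = 0.00504), and ribosomal protein genes fell in 14 of 39 (25 adjusted over the list alone, adjusted p = 4.43e-11). In all, 2518 genes changed, 1320 of them upward (3382 without the 6 libraries, 1687 of them upward). The response differed from that of parental cells for 1074 genes (1952 without the 6 libraries, 687 with a fit to its own libraries). G2/M genes responded more negatively in 34 of 39 (38 adjusted over the list alone, median -2.07, adjusted p = 3.89e-52), with RRM2 at -3.16 ± 0.21, CCNE2 at -3.03 ± 0.31 and CCND1 at 1.37 ± 0.14.

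**Figure D2:**
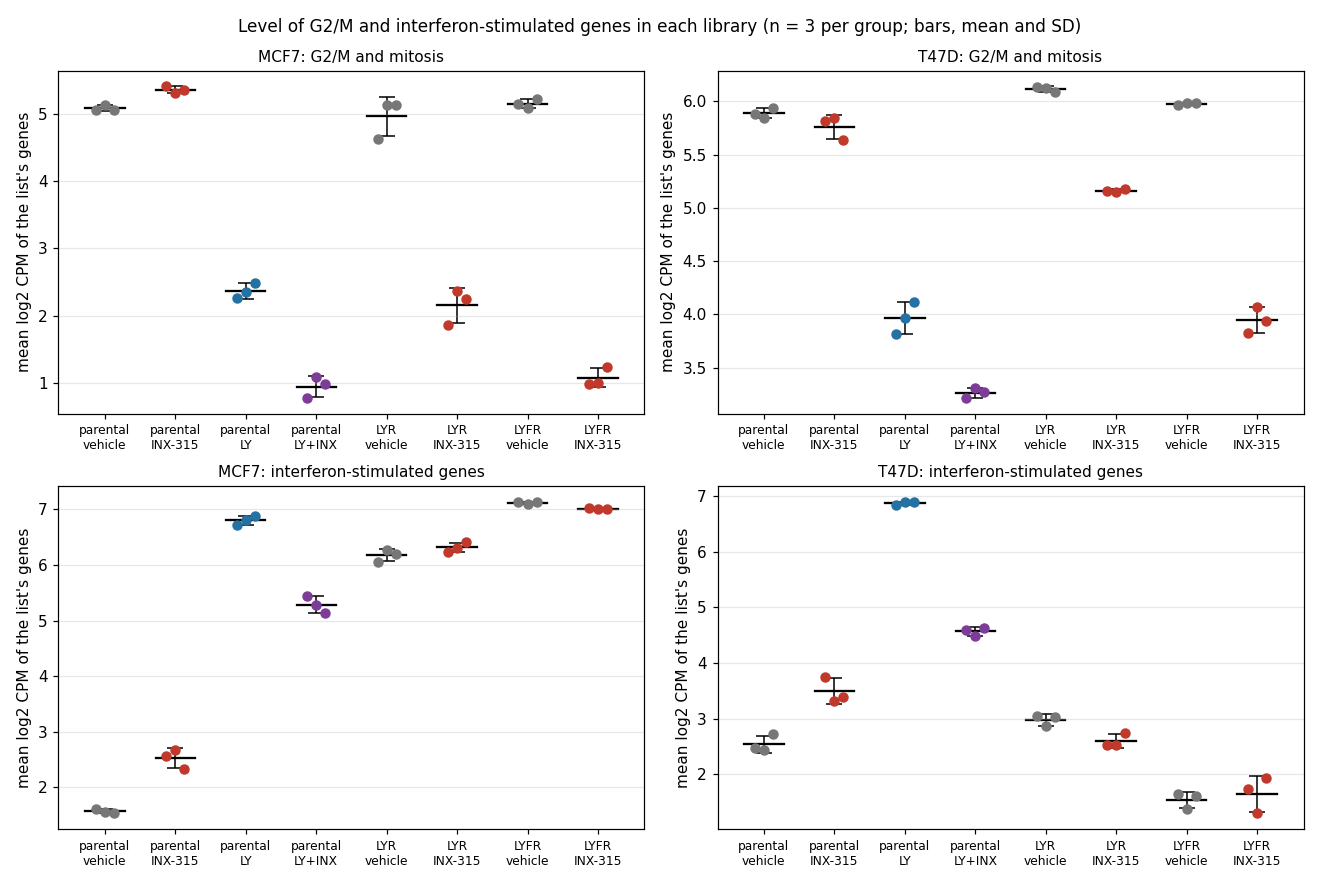
Mean log2 CPM over the members of the G2/M list and of the interferon-stimulated list (vertical axes) in each group of MCF7 and T47D (horizontal axes), where points are libraries and bars give the mean and SD over n = 3. In MCF7 the G2/M level falls with INX-315 in LYR and LYFR cells, where the list's medians are -2.89 and -4.44, and the interferon level is lower with both drugs than with LY (median -1.38).

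The responses to INX-315 were then set beside each other across genes, from comparisons that share no library. In MCF7 the log2 fold changes of LYR and LYFR cells correlated with Pearson's r = 0.681 (Spearman's rho = 0.597) over 12969 genes, and 1193 genes rose in both against 329 expected of independent lists, while 1034 fell in both against 286. Parental and LYR cells gave r = 0.199, with 495 genes raised in both against 192 expected, 141 lowered in both against 114, and 282 in opposite directions against 318. Parental and LYFR cells gave r = 0.250, with 611 genes raised in both against 216 expected, 140 lowered in both against 87.3, and 179 in opposite directions against 279. In T47D, LYR and LYFR cells gave r = 0.304 over 12575 genes, with 294 raised in both against 63.2 expected and 203 lowered in both against 36.0. Parental T47D cells gave r = 0.063 with LYR and 0.107 with LYFR cells, or 0.032 and 0.04 without replicate 3 of parental cells with INX-315. INX-315 alone and INX-315 added to LY gave r = -0.139 in MCF7 and -0.181 in T47D, with 97 and 30 genes changed in opposite directions against 26.4 and 4.51 expected. In MCF7, 21 genes rose in both against 9.16 expected and 5 fell in both against 11.3. In T47D, 5 rose in both against 2.12 and 4 fell in both against 1.81. All calls of a line come from 1 fit, so the lists of calls are not fully independent. The T47D value of r shrank to -0.07 without replicate 3 of parental cells with INX-315, to -0.097 without replicate 1 of parental cells with LY, and to -0.087 without the 6 libraries. Genes are not independent replicates, and r was computed for 6 pairs of conditions in each line. The 3 pairs per line that hold INX-315 added to LY were added after the other comparisons had been fixed. Without the filter on low counts r for LYR and LYFR cells was 0.256 in MCF7 and 0.084 in T47D. In MCF7 it was 0.068 for parental and LYR cells and 0.092 for parental and LYFR cells. For INX-315 alone and INX-315 added to LY it was -0.023 in MCF7 and -0.027 in T47D.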

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

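The 3 patterns weighed here were noticed in these data and then tested on them, and the tests of GC content, of scaling, of the response of neighbouring genes to LY, of windows without 1 library and of shuffled residuals were chosen only after the result was seen.

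In 6 libraries, many transcripts lay below both other libraries of their group, up to 1095 genes in replicate 1 of the MCF7 LYR vehicle arm, where 838 others lay above both. Total counts were the highest of their group in replicate 2 of parental MCF7 with INX-315 and replicate 1 of parental T47D with LY. The same held for replicate 1 of T47D LYFR with INX-315, so lower depth does not account for the low genes in these libraries. Libraries of the same group, thinned where they were larger, lost at most 5.71% as many genes. But each was also compared with the divergent library itself, which favours a low count. For the other libraries this test therefore cannot decide. The lost genes had transcript ends of lower GC content (a median of 38.8% against 44.2% in replicate 1 of the MCF7 LYR vehicle arm), but 82.5% of the lost genes over the 6 libraries stayed lost after a trend with GC content had been removed. On the genes that were not lost, all 6 libraries correlated best with a library of their own group. Leaving out the lost genes favours the own group, however. For replicate 3 of parental T47D with INX-315 the margin was small (r = 0.9394 against 0.9355 with another group). A swapped label is therefore not excluded by this test. An uneven recovery of transcripts while the libraries were made may be a technical cause, which counts alone cannot test.

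Interferon-stimulated genes were higher with INX-315 alone and lower when INX-315 was added to LY, with a difference between these effects of -2.80 (median log2) in MCF7 and -3.60 in T47D. The 6 libraries do not explain it, since without them each line kept at least 95.6% of its median. Of the members above the list's median level, 100% had a negative difference in each line. That level was a mean over all 24 libraries of a line, however. In parental MCF7 cells the list stood at 1.53 to 1.62 mean log2 CPM with vehicle, against 6.72 to 6.88 with LY. Members counted as strong can thus lie near the floor with vehicle, where they can hardly fall, so this test does not exclude an effect of low counts there. Normalization by a factor per library would shift all genes alike, but at most 1.80% of the genes outside the list had a difference as negative as the list's median in either line. A biological hypothesis is that the rise of interferon genes under LY may depend in part on CDK2 activity, which lowering CDK2 itself under LY would test, but in resistant MCF7 cells, where the list was higher than in parental cells, INX-315 did not lower it past the threshold (LYR 6 rises and 2 falls of 34, 6 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.411, 0.0349 as a rise without the filter to 0.683 over 8 alternatives; LYFR median -0.15, adjusted p = 0.175, 0.0269 as a fall without the filter to 0.490). In T47D LYR cells, where the list did not pass against parental cells (adjusted p = 0.0564, 0.0165 to 0.352 over 8 alternatives), INX-315 lowered it (6 falls of 35, 9 falls and 2 rises adjusted over the list alone, median -0.47, adjusted p = 0.000994, or adjusted p = 0.123 with an estimated correlation, 0.000568 to 0.123 over 8 alternatives).

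Neighbouring genes differed together between resistant and parental vehicle arms in 138 of 1044 windows tested over 4 comparisons, where the smallest p the shuffles can give is 1e-04. The windows at 5 to 10 and 10 to 15 Mb of chromosome 12, with CDKN1B in the latter, were lower in MCF7 LYR (medians of -1.58 and -1.47 relative to the genes of all windows, as for all windows below), MCF7 LYFR (-1.43 and -1.27), T47D LYR (-0.96 and -1.19) and T47D LYFR cells (-0.71 and -1.18). LY shifted 8.70% of the windows in parental cells in the same direction by at least 50% of the size. Among these is the window at 5 to 10 Mb of chromosome 12 in T47D LYFR cells, which stood at -0.38 with LY in parental T47D cells. But parental cells given LY for 7 days cannot stand for resistant cells grown with abemaciclib, and no parental arm had fulvestrant. A response to the drugs in the medium is therefore not excluded. Of the 138 windows, 113 are in comparisons that hold none of the 6 libraries, and of the 25 in MCF7 LYR cells 23 (92.0%) kept at least 50% of their size without replicate 1 of the vehicle arm, but not those at 0 to 5 Mb of chromosome 11 (0.42 to 0.08) and 140 to 145 Mb of chromosome 8 (0.48 to 0.10). Between the INX-315 arms of resistant and parental cells, which are other libraries, 87.0% kept the direction and at least 50% of the size. A lasting difference between the cells would give this, but so could the drugs if the INX-315 arms of the resistant cells held them. A change in copy number is a candidate explanation that was not tested, since no DNA was measured.

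Other results stood out because the effect of INX-315 differed between conditions by a test of the difference itself. In MCF7 that difference passed for 2717 genes between LYR and parental cells, 2089 between LYFR and parental cells and 1453 with and without LY. In T47D it passed for 372, 1074 and 594 genes. The median difference of the G2/M list was -3.23, -4.63 and -2.04 in MCF7 and -0.90, -2.07 and -0.63 in T47D, in the same order. Differences for LYR and LYFR cells cannot be told apart from an effect of the drugs in their vehicle arms.

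For these differences, the real split of the libraries was set beside 99 others. In MCF7, 1 of the 100 splits, the real one, gave as many genes for each of the 3 differences, with highest other counts of 2028, 1920 and 837 genes. In T47D, 2 of 100 splits gave 372 or more genes for LYR cells (highest other 402), 7 of 100 gave 1074 or more for LYFR cells (highest other 1483) and 1 of 100 gave 594 or more for LY (highest other 285). The share for T47D LYFR cells is not under 0.05, the limit set before, so by that rule chance remained possible there. These splits do not settle whether chance can be excluded, since a split that keeps the arms of 1 pair still holds a drug effect, and a split that mixes the arms of both adds the drug effects to the spread.

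The spread between libraries was therefore also tested by shuffling the residuals of the 8 group means over the 24 libraries of a line, which leaves no drug effect in a draw. Of 100 draws, the data included, 1 gave as many genes for each of the 6 differences, namely the data. A spread alike in all libraries thus did not give such counts. But residuals from means of 3 libraries are smaller than the full deviations. Shuffling also treats all libraries as equally spread, which the 6 divergent ones are not. This test therefore does not fully exclude the spread between libraries as the cause. The counts by limma and the highest of the other draws were 2733 and 912, 2041 and 1, and 1315 and 0 in MCF7, and 385 and 1, 1139 and 5, and 539 and 1 in T47D, in the order LYR, LYFR and LY.

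Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05, and in each the real split gave the only result as large (1 of 10). The real and the highest other counts in MCF7 were 1950 and 0 for INX-315 in parental cells, 5298 and 0 for LY, 5218 and 0 for both drugs, 312 and 0 for both drugs against LY, 4152 and 1501 for INX-315 in LYR cells, 3873 and 0 in LYFR cells, 4746 and 183 for LYR against parental cells, 5521 and 0 for LYFR against parental cells, and 4197 and 0 for INX-315 against LY. In T47D they were 189 and 2, 3589 and 0, 4238 and 0, 562 and 0, 980 and 0, 2518 and 1, 3927 and 0, 5190 and 0, and 3102 and 853, in the same order.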

How the results depend on the processing

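No test in this part was chosen after its result was seen except the fits without the 6 divergent libraries and the alternatives of the direct comparisons and of the correlations.

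Of 204 named pairs of a gene and a comparison, 194 kept their direction and their side of the threshold under every alternative run, and none reversed. The exceptions were 8 genes of parental T47D cells with INX-315 that lost their call in the fit to their own 6 libraries, CDKN1A in that comparison and RB1 in T47D LYR cells. Many of the named pairs were picked for large changes past the threshold in these same data. Their stability therefore does not describe the other calls. Of 247 list results, 62 changed under at least 1 alternative, most often with an estimated correlation (39 lost their call). DESeq2 size factors moved the median of all genes by at most 0.049. Depth limits weak genes, since 1 count stands for up to 0.400 CPM. In simulated data 43.5% of 2-fold differences between effects were called in MCF7, among genes above a set mean count, so this share does not describe weak genes.

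The G2/M list in vehicle arms lay so near 0 that its median changed sign or left 0. For MCF7 LYR against parental cells (0.00 in the test as reported) it was -0.013 with DESeq2 size factors, -0.032 without the filter, -0.030 with DESeq2's Wald test, -0.026 with a fit to its own libraries, and 0.043 without the 6 libraries, and without the filter camera called it lower (adjusted p = 0.0330). For MCF7 LYFR cells (0.003) it was -0.001 with DESeq2 size factors, without the filter and with DESeq2's test, and -0.008 with its own libraries. Without the filter, the senescence-associated secretory list stood at 0 in the MCF7 difference between LYFR and parental cells, and markers of other cell types at -1.01 in T47D LYR against parental cells. In the fit to its own libraries this last list had too few members for a test. Antigen presentation in MCF7 LYFR cells with INX-315 stood at 0.079 without the 6 libraries, against -0.002. The cause was not tested.

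Some counts moved by over 1.5 times with a fit to the libraries of the comparison alone, which takes the spread from those libraries only. In MCF7 these were both drugs against LY (312 to 1448), INX-315 in LYR cells (4152 to 933), LYR against parental cells (4746 to 1539) and the differences for LYR (2717 to 1455), LYFR (2089 to 3208) and LY (1453 to 2747). In T47D they were INX-315 in parental cells (189 to 0 in edgeR, with 954 of 11072 genes at an unadjusted p under 0.05 and 300 genes in DESeq2 over all 24 libraries), both drugs against LY (562 to 272), INX-315 in LYR cells (980 to 2502), the differences for LYFR (1074 to 687) and LY (594 to 184), and INX-315 against LY (3102 to 940). Fewer libraries alone would lower counts, which argues against this as the cause of the rises. The counts that fell were in comparisons that hold a library with 1095, 570 or 210 low genes, and those that rose hold none of these libraries. Without the filter the count for INX-315 in parental T47D cells was 352. A fit to the libraries of a comparison alone uses the same counts for them. The moves with that fit thus come from what a fit shares over libraries, such as the spread, filter and scaling. Which of these caused them was not tested.

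Without the 6 libraries, counts moved in MCF7 to 3353 for INX-315 in parental cells, 1303 for both drugs against LY, 3450 for the difference for LYFR and 2918 for that for LY. In T47D they moved to 509 for INX-315 in parental cells, 1100 for both drugs against LY, 2409 for INX-315 in LYR cells, 1106 for the difference for LYR and 1952 for that for LYFR. Both drugs against LY in MCF7 and INX-315 in T47D LYR cells hold none of the 6 libraries. Their own libraries did not change, so these moves come from what the fit shares over libraries, such as the spread, filter and scaling. Which of these it was, and the cause of the other moves, was not tested.

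Leaving out 1 library moved counts for MCF7 both drugs against LY (171 to 228, as reported 312) and in T47D for INX-315 in parental cells (62 to 340), both drugs against LY (302 to 653), INX-315 in LYR cells (595 to 688), the difference for LYR (239 to 506) and the difference for LY (319 to 953). The other 18 counts stayed within 1.5 times. All 12 correlations across genes kept their sign, apart from a value of 0 for LYR and both drugs in MCF7 without the filter, and all 12 were smaller in size without the filter. They moved by more than the SD of the values with 1 library left out in 80 of 144 fits with 1 library left out and for 9 of 12 without the 6 libraries. In T47D, parental cells and INX-315 added to LY went from -0.181 to -0.07 without T47D_PAR_INX replicate 3, to -0.097 without T47D_PAR_LY replicate 1 and to -0.087 without the 6 libraries. With DESeq2 size factors all 12 stayed within that SD.

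The replicate number was also used as a block. It moved no count by over 1.5 times (T47D parental cells with INX-315 179 against 189, MCF7 both drugs against LY 270 against 312), put the G2/M list of MCF7 LYR against parental cells at -0.015, and gave the interferon list of T47D LYR against parental cells an adjusted p = 0.0447 in camera. Libraries with the same number did not correlate more than others after their group means were removed (median r of -0.008 against 0.005 in MCF7, 0.004 against 0.001 in T47D), and the share that correlated best with their own number ran from 0 to 100% between comparisons, so the numbers were not taken to pair the samples.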

Other observations

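No test was chosen for this part after its result was seen, and the gene groups are those written before the data were examined, but which of them are described here was chosen after their values were seen.

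Ribosomal protein genes, which track the making of ribosomes, moved in most comparisons. With LY and INX-315 together, all 39 were lower than with vehicle in T47D (39 adjusted over the list alone, median -0.94, adjusted p = 4.60e-25 in camera) and 29 of 39 in MCF7 (29 adjusted over the list alone, median -0.65, adjusted p = 1.22e-10). INX-315 lowered 26 of 39 in MCF7 LYR cells (26 adjusted over the list alone, median -0.61, adjusted p = 1.18e-10) and 7 of 39 in MCF7 LYFR cells (6 adjusted over the list alone, median -0.34, adjusted p = 4.02e-05). In the vehicle arms, 26 of 39 were lower in T47D LYR than in parental cells (29 adjusted over the list alone, median -0.61, adjusted p = 9.07e-14), and 28 of 39 in MCF7 LYFR cells (29 adjusted over the list alone, median -0.72, adjusted p = 2.88e-10).

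Genes of lysosomes and drug handling moved with INX-315 in resistant MCF7 cells, and other groups moved in LYR or LYFR cells. Lysosome genes, which encode hydrolases and their pumps, rose in 16 of 26 and fell in 1 in LYFR cells (19 and 1 adjusted over the list alone, median 0.81, adjusted p = 7.65e-10 in camera). Drug handling and AHR targets rose in 11 of 14 there (11 adjusted over the list alone, median 1.65, adjusted p = 3.93e-08). Antigen presentation genes rose in 8 of 15 in LYR cells (8 adjusted over the list alone, median 0.67, adjusted p = 0.000151), but in LYFR cells 1 rose and 3 fell (1 and 3 adjusted over the list alone, adjusted p = 0.507). The rise in LYR cells rests in part on replicate 1 of the vehicle arm, which is 1 of the 6 divergent libraries. The list's mean log2 CPM was 5.72 there, against 6.40 and 6.46 in replicates 2 and 3. Cholesterol genes fell in 8 of 22 and rose in 1 in LYR cells (10 and 2 adjusted over the list alone, median -0.38, adjusted p = 0.00715), and in LYFR cells the list did not pass in camera (adjusted p = 0.113) but did without the filter (adjusted p = 0.0411) and in fry (adjusted p = 5.56e-05). The p53 targets rose in 9 of 28 and fell in 1 in LYFR cells (10 and 1 adjusted over the list alone, median 0.49, adjusted p = 0.000744).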
